A study of Homo sapiens with 12 samples.

How the data were processed

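The data are RNA sequencing counts from 12 libraries of total RNA, 6 from WiT49 and 6 from HEK293, with 3 DMSO and 3 QC6352 (25 nM, 72 h) libraries in each line, per the labels. RNA was isolated with a column kit, per the labels' protocols. The deposited values are whole-number read counts per gene symbol in 2 tables, 1 per line, with 50778 symbols each and no normalization, as the values show. The submitters' processing notes name the genome build GRCh37; the aligner, the annotation, the strand setting and the version of the counter are not given in the sources used here. Within groups, none of the 12 pairs of libraries was closer than separate libraries would be in a check for duplicated columns over genes with at least 20 counts in the pair. Groups were taken from the labels, and no library was left out. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

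Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr (minimum count 10), libraries were scaled with TMM factors, and each line was fitted by itself with a robust quasi-likelihood model of treatment. The difference between lines was the interaction of line and treatment in a fit of all 12 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and calls with an absolute log2 fold change of at least 1 were counted as well. Standard errors were derived from the log2 fold change and its F statistic. CPM are TMM-scaled, and shares of counts are unscaled. No spike-in was named, so every change is relative to the other genes of a library.

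Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 between genes, two-sided, with adjustment over the 34 lists that had at least 3 tested members. A further list, the mitochondrially encoded genes, had no member in the tables and could not be tested. Lists, tests and the rule for named genes were fixed before the data were examined. The rule names KDM4A to KDM4E, the 8 largest increases and 8 largest decreases per line, the 5 largest differences between lines in each direction, the 4 highest and 4 lowest genes in common, and up to 3 members per list and comparison by smallest p. Genes named as extremes needed an average log2 CPM of at least 2 and a name that is not that of a clone or pseudogene, and within lines no overlap of treated and control CPM. Some genes that the rule names are not reported here. Non-overlap arises by chance in 10% of unchanged genes with 3 libraries against 3. The lists cover the KDM4 family, other JmjC demethylases, H3K9 methylation machinery, ribosomal proteins of both subunits, ribosome biogenesis factors, RNA polymerase I, mitochondrial ribosomal proteins, translation factors, snoRNA hosts, MYC, p53, replication, mitosis, apoptosis, integrated stress response, endoplasmic reticulum chaperones, heat shock, cholesterol synthesis, glycolysis and hypoxia, interferon, extracellular matrix, nephron progenitors and epithelium, WNT, immediate early, neuronal and histone genes, oxidative phosphorylation, lysosome, immune, endothelial and fibroblast markers, and ZNF genes.

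The gene tests were tried on counts simulated from the control means, library sizes and spread of each line, with 200 changed genes per line. The changed genes were drawn only from those above a minimum expected count, so recovery was not tried for the lowest genes tested. The list test was tried in WiT49 only, where 0 of 30 unchanged lists were called. Those lists held randomly drawn genes that were simulated independently. Among real WiT49 lists the estimated correlation between genes reached 0.82 (replication-dependent histone genes). The trial therefore cannot show false calls that come from correlated members. At 1.5-fold, 2-fold and 4-fold, 83.6%, 91.0% and 100% of changed genes were recovered in WiT49 and 76.1%, 94.0% and 100% in HEK293, and for the difference between lines 69.2%, 82.3% and 98.4%. Unchanged genes made up 8.96%, 6.25% and 5.31% of the calls, in that order. These shares lie above the adjusted p threshold of 0.05. The biological coefficient of variation of the real libraries was 4.21%, 7.30% and 6.06%, in the same order. In the real data 69.4% of tested genes were called in WiT49 and 62.5% in HEK293, far more than the 200 simulated changes per line. Recovery, false calls and scaling were thus not tried with changes as widespread as the real ones. At depths of 37536360 to 83119304 counts per library, 21687 genes in WiT49 and 22256 in HEK293 passed the filter.

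Alternatives chosen before the data were examined were DESeq2 size factors, upper quartile factors, library size alone, no filter, a stricter filter (50 counts in 3 libraries), DESeq2 1.42.0's Wald test, limma-voom, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a fit without robust estimation, all libraries in 1 fit, and for lists an estimated correlation and fry. Protein-coding genes by their GENCODE 29 symbol, matched for 31647 of 50778 symbols, and other scalings of the list tests were chosen after seeing the data. Lengths and GC content came from the same release, by symbol only. Mapping, strand and splicing were not analysed here.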

Results

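RNA sequencing measured gene expression in 12 libraries of total RNA from 2 human cell lines. WiT49 was derived from an anaplastic Wilms tumour, a childhood kidney cancer, and HEK293 is a line from human embryonic kidney. Each line was grown for 72 h with 25 nM QC6352, an inhibitor of the KDM4 histone demethylases, or with the solvent DMSO. There were 4 groups of 3 libraries. KDM4 enzymes remove methyl groups from histone H3 at lysine 9 and lysine 36. The series title names sensitive cells, loss of KDM4 protein and pathways around ribosome biogenesis, and the labels do not say which line is the sensitive one. Total counts per library ran from 37536360 to 83119304 in WiT49 and from 56893684 to 77527627 in HEK293. The lines also differed in culture medium and in serum, so a difference between lines is also a difference between media. Fold changes below are QC6352 against DMSO on the log2 scale, with the standard error (SE) of the fit and n = 3 libraries per group.

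The KDM4 transcripts themselves came first, since they encode the target of the compound. KDM4A, which acts on both lysines, rose in WiT49 from 93.8 ± 2.41 to 128 ± 6.66 CPM (TMM-scaled; mean ± SD, n = 3) and in HEK293 from 77.2 ± 5.43 to 91.0 ± 2.70. KDM4C fell in WiT49 from 17.8 ± 0.54 to 9.99 ± 0.66 CPM, whereas in HEK293 it was at 38.9 ± 2.10 and 42.7 ± 2.92. KDM4B rose in HEK293 from 60.3 ± 9.93 to 88.0 ± 7.63 CPM and was at 30.04 ± 0.61 and 29.8 ± 0.89 in WiT49. KDM4D, the least abundant of the tested members, rose in HEK293 from 5.69 ± 0.24 to 9.74 ± 0.70 CPM and in WiT49 from 6.13 ± 0.31 to 7.21 ± 0.17. KDM4E was too low to test: its counts summed to 6 and 53 over the 3 DMSO and 3 QC6352 libraries of HEK293, and to 4 and 6 in WiT49.

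In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, the log2 fold changes in WiT49 were 0.44 ± 0.04 for KDM4A (adjusted p = 1.00e-11) and -0.01 ± 0.05 for KDM4B (adjusted p = 0.819). They were -0.84 ± 0.07 for KDM4C (adjusted p = 2.48e-14) and 0.24 ± 0.08 for KDM4D (adjusted p = 0.00898). In HEK293 they were 0.24 ± 0.06 for KDM4A (adjusted p = 0.00614) and 0.55 ± 0.10 for KDM4B (adjusted p = 4.93e-04). There KDM4C was at 0.13 ± 0.07 (adjusted p = 0.118) and KDM4D at 0.78 ± 0.09 (adjusted p = 1.02e-05). Where a gene passed, its 3 treated libraries all lay on the same side of its 3 controls. Of the 4 tested members, 2 rose and 1 fell in WiT49 and 3 rose in HEK293, with the same counts adjusted over the list alone. As a list, the KDM4 family had no call in WiT49, where its median was 0.11, its mean -0.04 and its test pointed up (camera adjusted p = 0.804). It had none in HEK293 (median 0.39, adjusted p = 0.102). The responses of the lines differed for KDM4C by -1.004 ± 0.10 (WiT49 minus HEK293; adjusted p = 3.66e-08). The difference was for KDM4B -0.59 ± 0.13 (adjusted p = 9.71e-04) and for KDM4D -0.57 ± 0.12 (adjusted p = 5.90e-04), and KDM4A did not pass over all genes (0.18 ± 0.08, adjusted p = 0.0791, or 0.0350 adjusted over the list alone). KDM4D in WiT49 lost its call without DMSO replicate 3 of that line (0.20, adjusted p = 0.0702), and the KDM4A difference passed without HEK293 DMSO replicate 1 (0.21, adjusted p = 0.0211). Scaled by library size alone, KDM4B in WiT49 turned to 0.22 (adjusted p = 4.57e-04) and KDM4C in HEK293 passed at 0.46 (adjusted p = 6.78e-04).

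**Figure D1:**
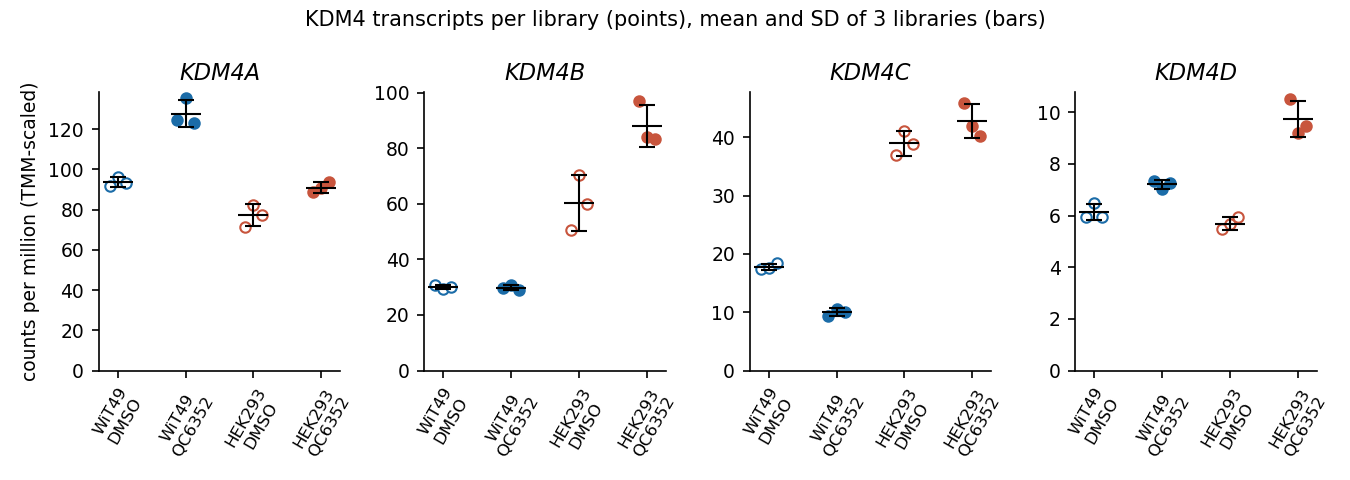
CPM (vertical axes, from 0) of KDM4A to KDM4D in the 12 libraries; open points are DMSO, filled points QC6352, blue WiT49 and red HEK293, and bars give the mean and SD of 3 libraries. KDM4C lies near 10 CPM in the treated WiT49 libraries and near 18 in their controls, whereas KDM4B in WiT49, whose sign turned when scaled by library size alone, is near 30 in both groups.

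The comparison in WiT49 asks which genes respond to QC6352 in the tumour line. OLR1, a receptor for oxidised low-density lipoprotein, rose most among genes above the abundance limit of the naming rule, from 0.28 ± 0.05 to 35.7 ± 1.12 CPM (log2 fold change 7.00 ± 0.11). The next increases were in IL7R, the alpha chain of the interleukin-7 receptor (5.78 ± 0.09), SALL4, a zinc finger factor of stem cells (5.03 ± 0.17), and CLIC5, a chloride intracellular channel protein (4.46 ± 0.13). TXK, a tyrosine kinase of the Tec family, rose by 4.30 ± 0.14. NPPB, the precursor of B-type natriuretic peptide, rose by 4.26 ± 0.07, PLCE1-AS1 by 4.22 ± 0.13 and DKK1, a secreted WNT antagonist, by 4.21 ± 0.06. PLCE1-AS1 is antisense to PLCE1, and because the strand setting of the counting is not given, its reads cannot be assigned to it with certainty.

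The largest decreases in WiT49 above that limit were in KRT85, a hair keratin (-4.40 ± 0.15), and HTRA1, a secreted serine protease (-3.98 ± 0.09). RORB, a nuclear receptor, was at -3.89 ± 0.13 and SLC7A11, the cystine importer, at -3.84 ± 0.08. GPC6, a glypican of the cell surface, fell by 3.79 ± 0.07, ANGPT1, a ligand of the receptor TEK, by 3.41 ± 0.07, and CDH6, a cadherin of the developing kidney, by 3.23 ± 0.05. EEF1A1, which brings aminoacyl-tRNA to the ribosome, went from 0.911 ± 0.0201% to 0.107 ± 0.00699% of all counts (mean ± SD, n = 3; log2 fold change -3.32 ± 0.05). Its reads can be shared with pseudogenes. Adjusted p in edgeR's quasi-likelihood test was at most 2.18e-22 for these 8 increases (NPPB) and at most 2.28e-24 for these 8 decreases (KRT85). All 6 libraries of the line showed these directions without overlap, as the rule for naming required. In total 15050 of 21687 tested genes passed the threshold, 7592 higher and 7458 lower. Of these, 4405 changed at least 2-fold, 2386 up and 2019 down. The medians of all genes are set near 0 by the TMM scaling. Library size alone moved the median by 0.230 and the split to 10784 higher of 15629, so all directions are relative to the bulk of genes.

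The genes of the ribosome fell together in WiT49. All 33 tested small subunit ribosomal proteins were lower (median -1.30), as were 46 of 47 large subunit ribosomal proteins with none higher (median -1.29). RPL10, of the large subunit, fell by 2.56 ± 0.05, RPL27A by 2.39 ± 0.05 and RPS3, at the mRNA entry, by 1.81 ± 0.05. Together the ribosomal protein genes went from 6.79 ± 0.0964% to 3.15 ± 0.143% of all counts (mean ± SD, n = 3), with reads that can be shared with their many pseudogenes. Translation factors fell as well (29 lower and 2 higher of 41, median -0.43, or -0.20 by library size alone), among them EIF3E (-1.54 ± 0.04) and EIF4B (-1.49 ± 0.04) of the initiation machinery. Among snoRNA host genes, whose introns carry the guide RNAs of rRNA modification, 12 were lower and 3 higher of 17 (median -0.36, or -0.13 by library size alone), led by ZFAS1 (-2.45 ± 0.05) and SNHG5 (-2.18 ± 0.04).

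Assembly factors of the ribosome moved much less in WiT49. Of 123 ribosome biogenesis factors 62 were lower and 24 higher, with a median of -0.11 that turned to 0.12 when scaled by library size alone. NPM1, an abundant nucleolar chaperone, fell by 1.25 ± 0.05, WDR74 by 1.16 ± 0.10, WDR36 by 0.69 ± 0.04 and FTSJ3, an rRNA methyltransferase, by 0.61 ± 0.04. The RNA polymerase I machinery, which transcribes rRNA, had no call (11 lower and 4 higher of 19, median -0.22, or 0.01 scaled by library size alone; adjusted p = 0.153), with TAF1D at -0.78 ± 0.04. Mitochondrial ribosomal proteins were lower in 44 and higher in 16 of 77 (median -0.15, or 0.08 by library size alone), with MRPL30 at -0.66 ± 0.04. Camera with its preset correlation called the lower lists with adjusted p = 6.36e-18 (large subunit), 6.45e-13 (small subunit) and 2.12e-06 (translation factors). It gave adjusted p = 0.0145 (snoRNA host genes), 0.0223 (ribosome biogenesis factors) and 0.0353 (mitochondrial ribosomal proteins). None held with the correlation estimated per list: adjusted p = 0.403 with an estimated correlation for both subunits and translation factors, 0.440 for snoRNA host genes, 0.516 for ribosome biogenesis factors and 0.729 for mitochondrial ribosomal proteins. Counts adjusted over the list alone were the same for each of these 7 lists. Ribosome biogenesis factors lost their call under a stricter filter (adjusted p = 0.124), upper quartile factors (0.0550) and library size alone (0.776). Mitochondrial ribosomal proteins did so there too (0.149, 0.0639 and 0.718) and without QC6352 replicate 1 (0.0735) or 2 (0.0547) of WiT49.

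**Figure D2:**
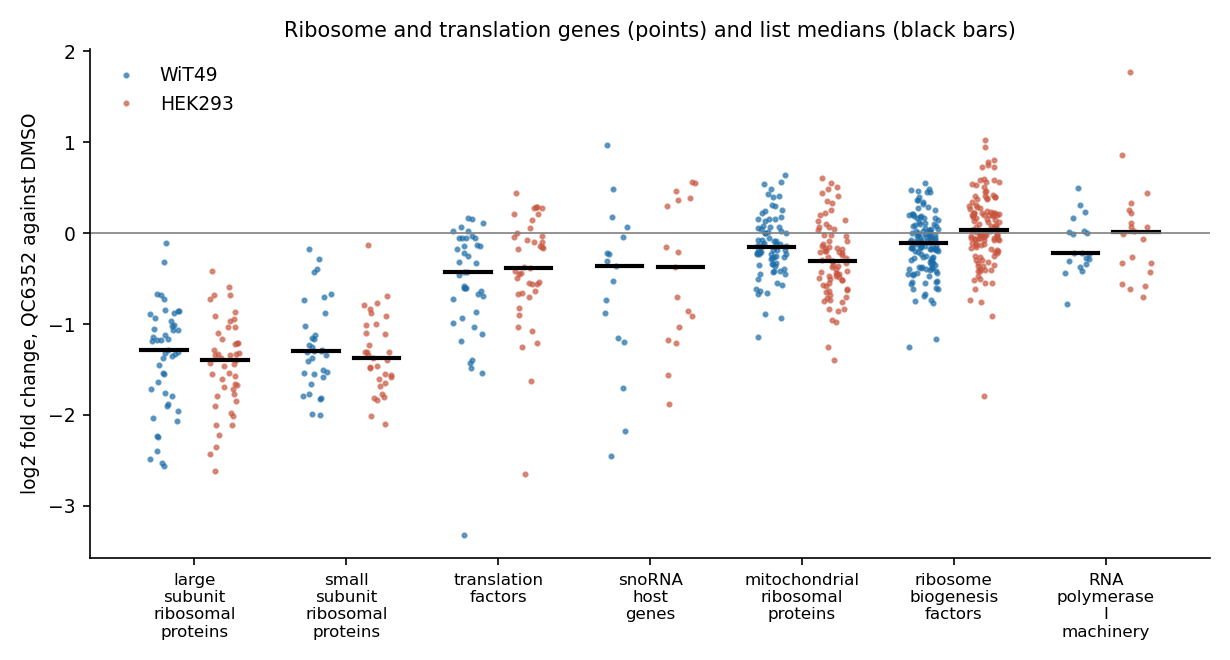
Log2 fold changes (vertical axis, QC6352 against DMSO) of single genes (points) in 7 lists around the ribosome in WiT49 (blue) and HEK293 (red), with black bars at the list medians. Both subunits lie below 0 in both lines with medians from -1.40 to -1.29; scaled by library size alone, the median turned positive for mitochondrial ribosomal proteins in both lines and for ribosome biogenesis factors and RNA polymerase I machinery in WiT49.

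In WiT49 8 further lists were called at the preset correlation, and none of them with the correlation estimated (adjusted p = 0.403 to 0.516 with an estimated correlation). Cholesterol synthesis genes were lower in 22 and higher in 1 of 24 (median -0.48). FDPS, which makes farnesyl diphosphate, fell by 0.96 ± 0.04, while SC5D, a late desaturase of the pathway, was the member that rose (0.74 ± 0.04). Replication-dependent histone genes were lower in 21 of 22 with none higher (median -1.22), with HIST1H2BK at -1.28 ± 0.05. Reads of near-identical histone genes can be shared. Nephron progenitor genes were lower in 11 and higher in 4 of 21 (median -0.49), among them the kidney transcription factor WT1 (-1.15 ± 0.05), MYCN (-0.79 ± 0.04) and the adhesion molecule NCAM1 (-1.17 ± 0.06). Immediate early genes rose in 16 and fell in 2 of 22 (median 1.05), with ATF3 (2.93 ± 0.06), JUN (1.71 ± 0.05) and DUSP1, a phosphatase of MAP kinases (1.69 ± 0.05). The other JmjC demethylases, relatives of KDM4, rose in 13 and fell in 2 of 19 (median 0.22), led by HR (1.55 ± 0.07). Oxidative phosphorylation genes were lower in 35 and higher in 3 of 46 (median -0.25, or -0.02 by library size alone; 36 and 4 adjusted over the list alone), with NDUFA10 of complex I at -0.95 ± 0.04. MYC-responsive growth genes were lower in 38 and higher in 11 of 58 (median -0.22, or 0.01 by library size alone). This list shares many members with the ribosome biogenesis factors, such as NPM1 and WDR74, so the calls of these lists are not independent. Mitosis genes were lower in 25 and higher in 7 of 45 (median -0.18, or 0.05 by library size alone), with BUB1B (-0.82 ± 0.04) and CDC20 (-0.71 ± 0.04), which govern the spindle checkpoint.

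Camera gave these WiT49 lists adjusted p = 5.52e-06 (cholesterol synthesis), 2.59e-08 (histones), 0.0351 (nephron progenitor) and 9.46e-05 (immediate early). The others had adjusted p = 0.0268 (JmjC), 9.46e-05 (oxidative phosphorylation), 0.00143 (MYC-responsive) and 0.0145 (mitosis). With the correlation estimated per list none passed: adjusted p = 0.403 with an estimated correlation for cholesterol synthesis, nephron progenitor, immediate early, JmjC and MYC-responsive genes, 0.450 for histones and 0.516 for oxidative phosphorylation and mitosis. Scaling by library size alone ended the calls of MYC-responsive genes (adjusted p = 0.0613) and mitosis genes (0.377), and a stricter filter that of mitosis genes (0.0724).

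The remaining lists had no call in WiT49 with the main settings. Glycolysis and hypoxia targets and ZNF genes passed under a stricter filter (adjusted p = 0.0427 and 0.0220), upper quartile factors (0.0490 and 0.0391) and library size alone (0.0160 and 0.00401). Integrated stress response genes were higher in 19 and lower in 12 of 35 (median 0.37; 20 and 12 adjusted over the list alone). The stress factor DDIT3 rose by 2.13 ± 0.05, TRIB3 by 1.00 ± 0.05 and CEBPG by 0.30 ± 0.04, against the fall of SLC7A11. Members of glycolysis and hypoxia targets were higher in 19 and lower in 10 of 34 (median 0.20), with NDRG1 at 2.48 ± 0.06 and the hexokinase HK2 at -0.66 ± 0.06. Interferon-stimulated genes were higher in 20 and lower in 11 of 39 (median 0.11), with STAT2 at -0.64 ± 0.04. The antigen-presenting HLA-B, whose reads can be shared with other HLA genes, was at 2.18 ± 0.04. p53 target genes were higher in 16 and lower in 7 of 29 (median 0.27; 17 and 7 adjusted over the list alone), with TP53I3 at 0.89 ± 0.06 and BBC3 at -0.06 ± 0.10 (adjusted p = 0.619). Apoptosis regulators were higher in 16 and lower in 10 of 28 (median 0.17), with BIRC3, an inhibitor of apoptosis, at -2.61 ± 0.05. WNT target genes were higher in 6 and lower in 8 of 20 (median 0.03, mean -0.02, test down), with NOTUM at -2.54 ± 0.07 and LEF1 at -1.22 ± 0.04. Nephron epithelial differentiation genes were higher in 15 and lower in 6 of 22 (median 0.80), and DNA replication genes in 14 and 25 of 49 (median -0.10, or 0.13 by library size alone; CDC45 -1.11 ± 0.05). ZNF genes were higher in 214 and lower in 122 of 453 (median 0.11; 215 and 124 adjusted over the list alone) and H3K9 methylation machinery in 4 and 8 of 16 (median -0.07, or 0.16 by library size alone; TRIM28 -0.61 ± 0.04). Extracellular matrix and EMT genes were higher in 20 and lower in 17 of 46 (median 0.02), with the matricellular CTGF and CYR61 at 2.26 ± 0.07 and 1.79 ± 0.13.

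Neuronal genes were higher in 7 and lower in 10 of 19 WiT49 members (median -0.39, or -0.15 by library size alone, mean 0.02, test down) and lysosome genes in 11 and 8 of 29 (median 0.01). The counts were for endoplasmic reticulum chaperones 3 and 11 of 19 (median -0.16, or 0.07 by library size alone) and for heat shock proteins 6 and 9 of 17 (median -0.20, or 0.03 by library size alone). Few markers of other cell types were tested. Immune cell markers were higher in 6 of 7 with none lower (median 0.76), endothelial markers higher in 3 and lower in 3 of 8 (median 0.11; FLT1 2.57 ± 0.06), and fibroblast and stromal markers higher in 6 and lower in 5 of 14 (median 0.06, mean -0.24, test down). Camera's adjusted p for the no-call lists of WiT49 ran from 0.0577 (glycolysis and hypoxia targets) to 0.987 (fibroblast and stromal markers). Without WiT49 DMSO replicate 3, glycolysis and hypoxia targets and nephron epithelial differentiation genes passed (both adjusted p = 0.0443). The former passed also without QC6352 replicate 1 (0.0453), and immune cell markers without QC6352 replicate 3 (0.0402).

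The comparison in HEK293 asks the same of an embryonic kidney line. LGR6, a receptor for R-spondins, rose from 0.35 ± 0.07 to 16.4 ± 1.31 CPM (log2 fold change 5.57 ± 0.14), and GLP2R, an intestinal peptide hormone receptor, by 5.52 ± 0.15. ACTBL2, an actin whose reads can be shared with other actins, rose by 5.40 ± 0.10 and ARL14, a small GTPase, by 5.14 ± 0.14. CGA, the alpha subunit of the glycoprotein hormones, went from 7.13 ± 1.09 to 251 ± 35.5 CPM (5.14 ± 0.13). NPPB rose by 4.64 ± 0.29, CPA4, a carboxypeptidase, by 4.54 ± 0.13 and SPINK4, a protease inhibitor, by 4.29 ± 0.12. Among genes above the abundance limit of the naming rule, the largest decrease was in IRS4, an insulin receptor substrate, from 493 ± 17.5 to 26.2 ± 0.74 CPM (-4.23 ± 0.07). HTRA1 fell by 3.69 ± 0.13, GPC6 by 3.59 ± 0.17, GPM6A, a neuronal membrane glycoprotein, by 3.52 ± 0.17 and ERBB4, a receptor tyrosine kinase, by 3.50 ± 0.14. PRKG1, a cGMP-dependent kinase, fell by 3.23 ± 0.10, the interferon-induced IFIT1 by 2.95 ± 0.30 and INSIG1, which holds back sterol-regulated transcription, by 2.80 ± 0.06.

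In edgeR's quasi-likelihood test, adjusted p was at most 3.84e-08 for these 8 increases in HEK293 (NPPB) and at most 1.25e-05 for these 8 decreases (IFIT1). All 6 libraries of the line showed these directions without overlap, as the rule for naming required. In total 13915 of 22256 tested genes passed, 7093 higher and 6822 lower. Of these, 4388 changed at least 2-fold, 2812 up and 1576 down. Scaled by library size alone, the median of all genes moved by 0.322 and 11391 of 14833 calls were higher. The controls of HEK293 differed among themselves in 4 abundant short RNAs, which held 16.7%, 11.1% and 13.8% of counts in DMSO replicates 1, 2 and 3 against 6.68 ± 0.379% under QC6352 (mean ± SD, n = 3). Without DMSO replicate 1, 13708 genes passed.

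Ribosomal protein genes fell in HEK293 as well: 47 of 47 large subunit ribosomal proteins were lower (median -1.40) and 32 of 33 small subunit ribosomal proteins (median -1.37; 33 adjusted over the list alone). RPL23 fell by 2.43 ± 0.07, RPL27A by 2.35 ± 0.08, RPL10 by 2.01 ± 0.07 and RPS3 by 1.82 ± 0.07. The group went from 7.73 ± 0.383% to 3.68 ± 0.0766% of counts, again with reads that pseudogenes can share. EEF1A1 went from 1.17 ± 0.0966% to 0.235 ± 0.00712% of counts (log2 fold change -2.65 ± 0.09). EIF3E fell by 1.63 ± 0.07, and of 41 translation factors 25 were lower and 6 higher (median -0.38, or -0.06 by library size alone; 25 and 7 adjusted over the list alone). Ribosome biogenesis factors did not fall as a list: 45 were higher and 30 lower of 123 (median 0.03, adjusted p = 0.511). By library size alone the list was called higher (adjusted p = 0.0139). FTSJ3 (0.95 ± 0.08) and the helicase DDX21 (0.54 ± 0.05) rose, NPM1 (-0.91 ± 0.07) and WDR74 (-1.79 ± 0.12) fell, and WDR36 was at -0.06 ± 0.06 (adjusted p = 0.383), or 0.26 by library size alone. RNA polymerase I machinery had no call (6 higher and 8 lower of 20, median and mean 0.01, test down, adjusted p = 0.822), although RRN3, its initiation factor, rose by 0.86 ± 0.06. Mitochondrial ribosomal proteins were lower in 49 and higher in 11 of 77 (median -0.31, or 0.02 by library size alone; 50 and 11 adjusted over the list alone), with MRPL30 at -1.25 ± 0.08. snoRNA host genes were lower in 10 and higher in 5 of 17 (median -0.37, or -0.05 by library size alone; adjusted p = 0.102), with SNHG5 at -1.88 ± 0.09.

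Camera's adjusted p in HEK293 was 4.72e-20 for the large subunit, 3.05e-14 for the small subunit, 6.93e-04 for translation factors and 1.00e-04 for mitochondrial ribosomal proteins, all lower. They had adjusted p = 0.330, 0.369, 0.136 and 0.518 with an estimated correlation, in that order. Without HEK293 DMSO replicate 2, snoRNA host genes passed (adjusted p = 0.0450), and so they did by library size alone (0.0364).

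In HEK293 15 further lists were called at the preset correlation, and none of them with the correlation estimated (adjusted p = 0.0769 to 0.712 with an estimated correlation). Integrated stress response genes rose in 31 of 36 with none lower (median 1.06), among them DDIT3 (2.67 ± 0.09), the pseudokinase TRIB3 (2.34 ± 0.07), CEBPG (1.45 ± 0.05) and SLC7A11 (1.40 ± 0.12). All 25 cholesterol synthesis genes were lower (median -1.02), with HMGCS1, an early enzyme of the pathway, at -2.14 ± 0.07. Interferon-stimulated genes were lower in 27 and higher in 6 of 41 (median -0.66; 28 and 6 adjusted over the list alone), with STAT2, a transducer of interferon signals, at -1.13 ± 0.08. p53 target genes rose in 19 and fell in 5 of 30 (median 0.38), with TP53I3 at 1.70 ± 0.09 and the BH3-only gene BBC3 at 1.52 ± 0.08. DNA replication genes were lower in 33 and higher in 6 of 49 (median -0.37, or -0.04 by library size alone), with RRM2, a subunit of ribonucleotide reductase, at -1.49 ± 0.06 and CDC45, of the replicative helicase, at -1.40 ± 0.06. Neuronal genes rose in 13 and fell in 4 of 18 (median 1.14; 14 and 4 adjusted over the list alone), with the neurofilament NEFH at 2.06 ± 0.10 and the synaptic SNAP25 at 1.21 ± 0.11. Nephron epithelial differentiation genes rose in 17 and fell in 1 of 23 (median 0.56), with the endocytic receptor CUBN at 2.12 ± 0.12. Immediate early genes rose in 20 and fell in 2 of 23 (median 1.13; ATF3 1.78 ± 0.08, DUSP1 1.13 ± 0.07). The other JmjC demethylases rose in 13 of 19 with none lower (median 0.39; HR 1.63 ± 0.16, KDM5B 0.68 ± 0.06).

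Oxidative phosphorylation genes were lower in 39 of 46 HEK293 members with none higher (median -0.52, or -0.19 by library size alone; 41 lower adjusted over the list alone), with COX7C at -1.21 ± 0.07. Replication-dependent histone genes were lower in 21 of 23 (median -1.01), with HIST1H3A at -1.99 ± 0.07. Heat shock proteins were lower in 13 of 18 with none higher (median -0.30, or 0.02 by library size alone; 13 and 1 adjusted over the list alone), with HSPA8 at -1.16 ± 0.07. Mitosis genes were lower in 20 and higher in 5 of 45 (median -0.15, or 0.17 by library size alone). ZNF genes rose in 202 and fell in 102 of 461 (median 0.15; 203 and 105 adjusted over the list alone), with ZNF560 at 3.34 ± 0.14 and ZNF711 at -2.55 ± 0.07. Endothelial markers rose in 5 and fell in 1 of 10 (median 0.79; FLT1 0.81 ± 0.07). Camera's adjusted p was 1.15e-08 for integrated stress response, 3.19e-11 for cholesterol synthesis, 0.00261 for interferon-stimulated genes, 0.00150 for p53 targets, 1.31e-04 for DNA replication and 0.0126 for neuronal genes. It was 2.51e-04 for nephron epithelial differentiation, 1.64e-06 for immediate early genes, 0.00181 for JmjC demethylases and 2.49e-09 for oxidative phosphorylation. For the rest it was 5.33e-09 for histones, 0.00372 for heat shock proteins, 0.0224 for mitosis genes, 0.0195 for ZNF genes and 0.0224 for endothelial markers. With the correlation estimated none passed: adjusted p = 0.0769 with an estimated correlation for cholesterol synthesis, 0.124 for DNA replication and 0.278 for immediate early genes. It was 0.314 with an estimated correlation for integrated stress response, neuronal, nephron epithelial, histone and endothelial lists and 0.330 for heat shock proteins. It was 0.411 for oxidative phosphorylation, 0.457 for ZNF genes, 0.518 for p53 targets and JmjC demethylases, 0.619 for interferon-stimulated genes and 0.712 for mitosis genes. The estimated correlation itself was 0.011 for cholesterol synthesis and -0.011 for DNA replication, near or below the preset 0.01. The loss of these 2 calls therefore does not show correlation among their members. Mitosis genes also lost their call without QC6352 replicate 1 (adjusted p = 0.126), under a stricter filter (0.105), upper quartile factors (0.0712) or library size alone (0.515). ZNF genes lost it without DMSO replicate 2 (0.0685) or 3 (0.0689). A stricter filter and library size alone ended the calls of neuronal genes (0.0678 and 0.114) and endothelial markers (0.0759 and 0.1). Library size alone ended that of heat shock proteins (0.132).

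Lists without a call in HEK293 were MYC-responsive growth genes (18 higher and 22 lower of 58, median -0.02, or 0.30 by library size alone; TMEM97 -1.77 ± 0.06, HK2 1.21 ± 0.10) and nephron progenitor genes (9 and 5 of 26, median 0.13; MYCN -1.23 ± 0.10). WNT target genes were higher in 8 and lower in 1 of 19 (median 0.09), and passed by library size alone (adjusted p = 0.0428). Apoptosis regulators were higher in 12 and lower in 7 of 28 (median 0.11; BIRC3 1.64 ± 0.11) and glycolysis and hypoxia targets in 12 and 12 of 34 (median 0.07; 12 and 13 adjusted over the list alone). Extracellular matrix and EMT genes were higher in 22 and lower in 11 of 44 (median 0.13; CTGF 2.46 ± 0.14, CYR61 1.89 ± 0.08). H3K9 methylation machinery was higher in 6 and lower in 3 of 16 (median 0.11), and endoplasmic reticulum chaperones in 5 and 9 of 19 (median -0.15, or 0.18 by library size alone; 5 and 10 adjusted over the list alone). Lysosome genes were higher in 12 and lower in 7 of 29 (median 0.05), immune cell markers in 5 and 0 of 8 (median 1.04) and fibroblast and stromal markers in 5 and 3 of 11 (median 0.03). Camera's adjusted p for these lists of HEK293 ran from 0.0610 (immune cell markers) to 0.745 (fibroblast and stromal markers). Leaving out 1 library let immune cell markers pass without DMSO replicate 2 (0.0428) or QC6352 replicate 2 (0.0367), and the KDM4 family without DMSO replicate 2 (0.0428) or QC6352 replicate 3 (0.0419).

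**Figure D3:**
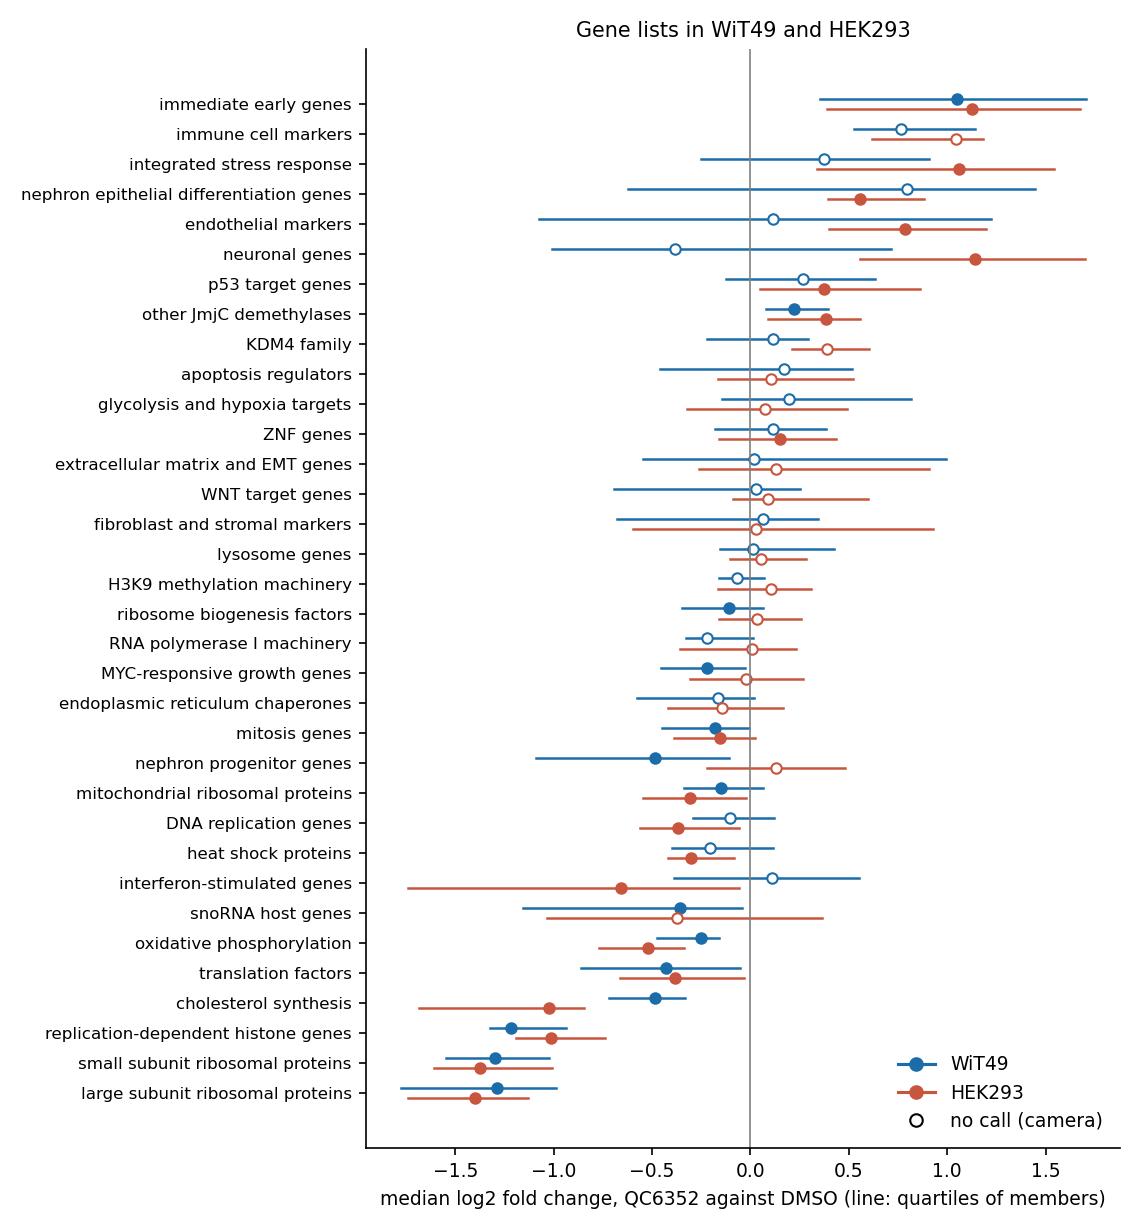
Median log2 fold change (horizontal axis, QC6352 against DMSO) of each gene list in WiT49 (blue) and HEK293 (red), with lines from the lower to the upper quartile of members and filled points for lists called by camera with its preset correlation, 14 in WiT49 and 19 in HEK293. Both ribosomal subunits lie lowest in both lines, and immediate early genes lie highest in WiT49 and neuronal genes in HEK293; scaled by library size alone, medians turned from below to above 0 in both lines for mitochondrial ribosomal proteins, mitosis, MYC-responsive, heat shock and endoplasmic reticulum chaperone genes, and in WiT49 for ribosome biogenesis factors, RNA polymerase I machinery, DNA replication genes and H3K9 methylation machinery.

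The overlap asks which changes the lines have in common. NPPB rose in both (4.26 ± 0.07 in WiT49, 4.64 ± 0.29 in HEK293), as did ANKRD1, a muscle stress protein (4.20 ± 0.08 and 3.70 ± 0.12), the keratin KRT80 (2.62 ± 0.05 and 2.95 ± 0.17) and CLIC5 (4.46 ± 0.13 and 1.08 ± 0.09). HTRA1 (-3.98 ± 0.09 and -3.69 ± 0.13), GPC6 (-3.79 ± 0.07 and -3.59 ± 0.17), EEF1A1 (-3.32 ± 0.05 and -2.65 ± 0.09) and GPM6A (-1.78 ± 0.08 and -3.52 ± 0.17) fell in both. Of 19761 genes tested in both lines, 3719 were higher in both, where independent lists of those sizes would share 2088, and 4286 were lower in both, where independent lists would share 2338. Opposite calls were fewer, with 853 genes higher in WiT49 and lower in HEK293 and 813 the other way, against 2290 and 2132 for independent lists. Fisher's exact test, one-sided, gave log10 p = -598 for shared increases and -816 for shared decreases. The test takes genes as independent, which they are not, so these values only describe the overlap. Across the 19761 genes the log2 fold changes of the lines had a Pearson correlation of 0.60 and a Spearman correlation of 0.56. These too describe the genes only, since genes are not independent replicates.

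**Figure D4:**
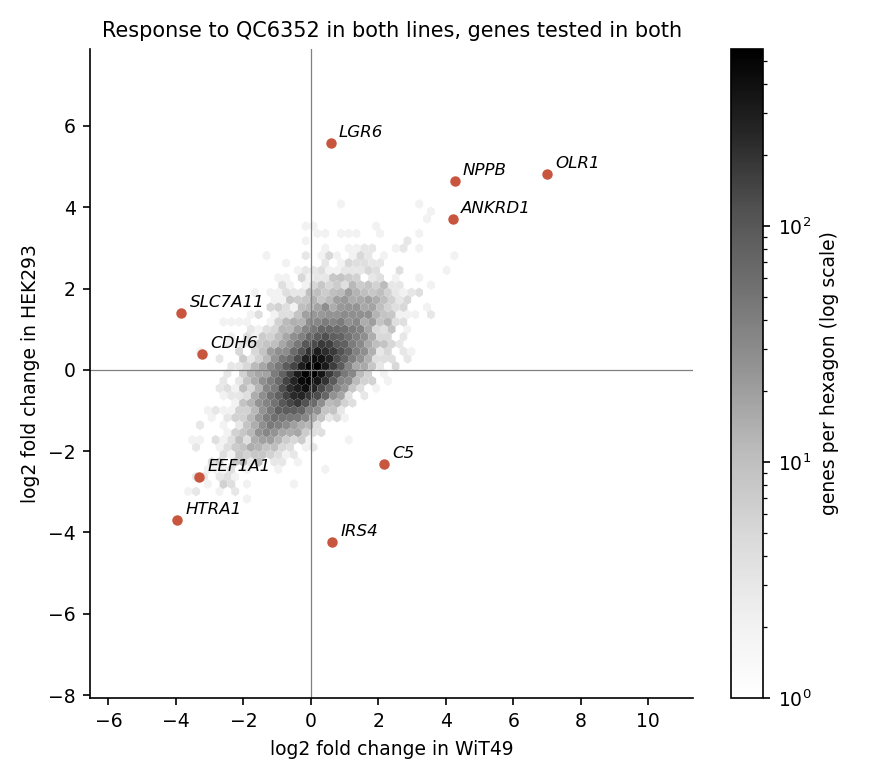
Log2 fold change in WiT49 (horizontal axis) against HEK293 (vertical axis) for the 19761 genes tested in both lines, shaded by the number of genes per hexagon on a log scale, with named genes in red. NPPB and ANKRD1 lie high in both lines and HTRA1 and EEF1A1 low in both, whereas SLC7A11 was lower in WiT49 and higher in HEK293 and C5 was higher in WiT49 and lower in HEK293.

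The difference between lines, WiT49 minus HEK293, was tested as an interaction over all 12 libraries. SLC7A11 differed most among well-counted genes on the lower side (-5.26 ± 0.16), falling in WiT49 and rising in HEK293, followed by LGR6 (-5.01 ± 0.22). On the higher side stood IFI44L, an interferon-induced gene (5.51 ± 0.88; -0.15 ± 0.08 in WiT49 and -5.70 ± 0.68 in HEK293), IRS4 (4.86 ± 0.41, though only 0.15 CPM in WiT49 controls), the complement component C5 (4.45 ± 0.16; 2.18 ± 0.06 and -2.31 ± 0.16) and the aggrecanase ADAMTS5 (3.83 ± 0.14; 3.51 ± 0.09 and -0.36 ± 0.09). Largest adjusted p among these 6 was 9.16e-04 (IFI44L; edgeR quasi-likelihood, Benjamini-Hochberg). The rule also named ELAVL2, H2AFJ, TNNT2 and ZC3HAV1L, for which no fold is given because a line had next to no counts: over 3 DMSO and 3 QC6352 libraries, ELAVL2 summed to 0 and 12 and H2AFJ to 4 and 0 in WiT49, and TNNT2 to 0 and 21 and ZC3HAV1L to 0 and 8 in HEK293. In total 9799 of 24551 tested genes passed, 4656 with a more positive response in WiT49 and 5143 in HEK293, and 3028 of them differed by at least 2-fold. This fit also tests genes that the filter of a line by itself left out, whereas 19761 genes were tested in both lines. For genes with next to no counts in a line, the difference rests on the response of the other line, and their share of the calls was not counted. Without HEK293 DMSO replicate 1, 9593 passed.

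By list, 13 of 34 differed between lines at the preset correlation, and only cholesterol synthesis also did with the correlation estimated. Cholesterol synthesis genes fell less in WiT49 (19 higher and 1 lower of 25, median difference 0.52), with differences of 2.16 ± 0.07 for INSIG1 and 1.64 ± 0.07 for HMGCS1. Interferon-stimulated genes were higher by difference in 27 and lower in 4 of 41 (median 0.79; 29 and 4 adjusted over the list alone; adjusted p = 0.356 with an estimated correlation), with IFIT1 at 3.52 ± 0.41 and HLA-B at 1.80 ± 0.07. Integrated stress response genes were lower in 28 and higher in 2 of 36 (median -0.60; 28 and 3 adjusted over the list alone; adjusted p = 0.302 with an estimated correlation), with TRIB3 at -1.37 ± 0.09 and CEBPG at -1.18 ± 0.06. Ribosome biogenesis factors were lower in 60 and higher in 8 of 123 (median -0.21; 62 and 11 adjusted over the list alone), with FTSJ3 at -1.59 ± 0.09, DDX21 at -0.73 ± 0.07 and WDR36 at -0.67 ± 0.07. The ribosomal proteins themselves had no call. The large subunit ribosomal proteins had a median difference of 0.05, or -0.01 by library size alone (14 higher and 10 lower of 47, 15 and 10 adjusted over the list alone). The small subunit ribosomal proteins had 0.09, or 0.02 by library size alone (7 and 4 of 33). MYC-responsive growth genes, which share many members with the ribosome biogenesis factors, were lower in 29 and higher in 5 of 58 (median -0.19; 30 and 6 adjusted over the list alone; HK2 -1.90 ± 0.12, against TMEM97 at 1.498 ± 0.07). Translation factors were lower in 19 and higher in 5 of 41 (median -0.15), with the poly(A)-binding PABPC1, whose reads can be shared with its paralogs, at -1.09 ± 0.10 and EIF4B at -0.62 ± 0.07. DNA replication genes were higher in 24 and lower in 7 of 49 (median 0.19; 25 and 7 adjusted over the list alone; RRM2 0.81 ± 0.08) and oxidative phosphorylation genes in 24 and 2 of 46 (median 0.26; 25 and 3 adjusted over the list alone). Mitochondrial ribosomal proteins were higher in 31 and lower in 11 of 77 (median 0.14) and glycolysis and hypoxia targets in 21 and 8 of 34 (median 0.31; 22 and 9 adjusted over the list alone; NDRG1 2.31 ± 0.10). Nephron progenitor genes were lower in 12 and higher in 3 of 25 (median -0.31; NCAM1 -1.43 ± 0.11, WT1 -1.37 ± 0.11). WNT target genes were lower in 12 and higher in 5 of 20 (median -0.49; NOTUM -2.50 ± 0.15, LEF1 -1.25 ± 0.08, against DKK1 at 2.94 ± 0.12) and neuronal genes in 12 and 4 of 22 (median -0.80; SNAP25 -1.96 ± 0.15).

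Camera on the difference gave adjusted p = 8.57e-08 for cholesterol synthesis, the only list that also passed with the correlation estimated (adjusted p = 0.0302 with an estimated correlation). The other adjusted p, each with its value under an estimated correlation after it, were 1.79e-07 and 0.356 (interferon), 4.40e-08 and 0.302 (integrated stress response), 1.69e-04 and 0.356 (ribosome biogenesis factors) and 0.00414 and 0.356 (MYC-responsive). They were 0.0472 and 0.452 (translation factors), 0.00150 and 0.235 (DNA replication), 8.79e-04 and 0.612 (oxidative phosphorylation) and 0.0320 and 0.803 (mitochondrial ribosomal proteins). They were 0.00659 and 0.356 (glycolysis and hypoxia), 0.0163 and 0.356 (nephron progenitor), 0.0338 and 0.452 (WNT targets) and 0.00448 and 0.356 (neuronal). Calls of 3 lists hung on single libraries. Translation factors lost theirs without WiT49 DMSO replicate 2 (0.0690), WiT49 QC6352 replicate 1 (0.126), HEK293 DMSO replicate 2 (0.0608) or HEK293 QC6352 replicate 2 (0.0566) or 3 (0.0540). WNT target genes lost theirs without WiT49 DMSO replicate 1 (0.0515) or 2 (0.0531) or QC6352 replicate 3 (0.0720). Mitochondrial ribosomal proteins lost theirs without WiT49 DMSO replicate 2 (0.0531) or 3 (0.0710), WiT49 QC6352 replicate 3 (0.138), HEK293 DMSO replicate 1 (0.112) or HEK293 QC6352 replicate 3 (0.0597). Library size alone ended the calls of mitochondrial ribosomal proteins (0.0867) and WNT target genes (0.0673), a stricter filter those of translation factors (0.0891) and WNT target genes (0.0512), and DESeq2 size factors that of translation factors (0.0553).

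The difference between lines had no call for p53 target genes (median -0.16; BBC3 -1.61 ± 0.13), other JmjC demethylases (-0.11; KDM5B -0.61 ± 0.07), H3K9 methylation machinery (-0.20; TRIM28 -0.51 ± 0.09), RNA polymerase I machinery (-0.15; RRN3 -0.59 ± 0.07) or the KDM4 family (-0.58). Nor had it for snoRNA host genes (-0.26; ZFAS1 -1.32 ± 0.17), mitosis genes (-0.07), endoplasmic reticulum chaperones (-0.08), heat shock proteins (0.12, or 0.06 by library size alone; HSPA8 0.63 ± 0.08) or histones (-0.14). The same held for nephron epithelial differentiation genes (-0.12; CDH6 -3.64 ± 0.11), immune cell (-0.01), endothelial (-0.40; FLT1 1.73 ± 0.09) and fibroblast markers (-0.79) and ZNF genes (-0.10; ZNF560 -3.03 ± 0.14, ZNF711 2.52 ± 0.08). Median, mean and test disagreed in sign for apoptosis regulators (0.13, -0.15, up; BIRC3 -4.28 ± 0.11), extracellular matrix and EMT genes (0.06, or -0.00 by library size alone, -0.15, up), immediate early genes (0.22, -0.07, up; JUN 1.40 ± 0.09) and lysosome genes (-0.11, 0.02, down). Camera's adjusted p for these lists ran from 0.0706 (heat shock proteins) to 0.975 (lysosome genes), and heat shock proteins passed without WiT49 QC6352 replicate 1 (0.0436).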

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

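The genes and lists in this part were singled out because the responses of WiT49 and HEK293 differed in the planned interaction test. The fall of ribosomal proteins in both lines is weighed for its size, and the lists of both subunits had no call in that test. Groups of 3 libraries are too small for a test of outlying samples. The tests of explanations and the other splits of the libraries were chosen only after the results were seen. In total 9799 genes passed the threshold of that difference, among them genes with next to no counts in a line. Splitting the libraries of each line otherwise, in 100 combinations, gave at most 3154 genes (1 of 100 as large, the real one), and for the 3028 genes differing at least 2-fold at most 1486 (1 of 100). The other combinations mix treated and control libraries within groups, which can widen the spread and lower the counts, so the comparison by itself does not exclude chance. For the 8005 genes called alike in both lines the comparison decides nothing (highest other 0, 1 of 100), since each other combination held a division of a line without any call. Nor is chance excluded for the number of gene lists, where 10 of 100 combinations called at least the 13 lists of the real division, up to 18. Within a line the 10 splits are too few for a share under 0.05. The real values and the highest others were 15050 and 0 genes, 4405 and 0 at 2-fold, and 14 and 13 lists in WiT49 (1 split as large in each), and 13915 and 0, 4388 and 0, and 19 and 19 lists in HEK293 (1, 1 and 2 as large).

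Of 13 lists called at the preset correlation, only cholesterol synthesis kept its call with the correlation estimated (adjusted p = 0.0302). Median log2 differences (WiT49 minus HEK293) were -0.80 for neuronal genes, -0.60 for the integrated stress response, -0.49 for WNT targets, -0.31 for nephron progenitor genes, -0.21 for ribosome biogenesis factors, -0.19 for MYC-responsive genes and -0.15 for translation factors. They were 0.14 for mitochondrial ribosomal proteins, 0.19 for DNA replication, 0.26 for oxidative phosphorylation, 0.31 for glycolysis and hypoxia targets, 0.52 for cholesterol synthesis and 0.79 for interferon-stimulated genes. Of the genes given with a fold change in the text, 79 passed the test of the difference and 28 did not. ELAVL2, H2AFJ, TNNT2 and ZC3HAV1L, given without a fold, passed as well and are not among the 79.

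Genes whose response was more negative in WiT49 included, on the log2 scale, KDM4B (-0.59), KDM4C (-1.004) and KDM4D (-0.57) of the target family. Among genes of the ribosome and translation were EEF1A1 (-0.71), RPL10 (-0.59), NPM1 (-0.37), WDR36 (-0.67), FTSJ3 (-1.59), DDX21 (-0.73), RRN3 (-0.59), EIF4B (-0.62), PABPC1 (-1.09), EEF1D (-0.35), ZFAS1 (-1.32) and SNHG5 (-0.34). Stress, p53 and apoptosis genes were SLC7A11 (-5.26), TRIB3 (-1.37), CEBPG (-1.18), DDIT3 (-0.57), BBC3 (-1.61), TP53I3 (-0.84) and BIRC3 (-4.28). Developmental and WNT genes were CDH6 (-3.64), WT1 (-1.37), NCAM1 (-1.43), NOTUM (-2.50), LEF1 (-1.25), LGR6 (-5.01), RORB (-2.29), ANGPT1 (-1.69), SNAP25 (-1.96) and NEFH (-1.13). The others were HK2 (-1.90), BUB1B (-0.48), CDC20 (-0.26), HIST1H2BK (-0.25), KDM5B (-0.61), TRIM28 (-0.51), ZNF560 (-3.03), ACTBL2 (-3.44), CPA4 (-2.92), IGFBP3 (-1.43) and AMOTL2 (-0.69).

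Genes whose response was more positive in WiT49 included the sterol genes INSIG1 (2.16), HMGCS1 (1.64), SC5D (1.64) and TMEM97 (1.498), and the interferon genes IFIT1 (3.52), IFI44L (5.51), HLA-B (1.80) and STAT2 (0.46). Signalling and secreted proteins were IL7R (3.01), DKK1 (2.94), TXK (1.51), IRS4 (4.86), ERBB4 (2.44), PRKG1 (1.30), FLT1 (1.73), C5 (4.45), ADAMTS5 (3.83), TGFB2 (0.59), GPM6A (1.70) and CLIC5 (3.35). Growth, stress and early response genes were RRM2 (0.81), CDC45 (0.26), MYCN (0.41), ATF3 (1.12), JUN (1.40), DUSP1 (0.53), HSPA8 (0.63), NDRG1 (2.31), COX7C (0.52), MRPL30 (0.56) and WDR74 (0.60). The others were SALL4 (2.42), ZNF711 (2.52), HIST1H3A (0.99) and PLCE1-AS1 (4.58). PLCE1-AS1 was too low to test in HEK293 by itself, with 21 counts in all over its DMSO libraries and 21 over its QC6352 libraries. ANKRD1 (0.46) passed with all libraries but not without any of the 8 libraries numbered 1 or 3, where its difference was 0.32 to 0.50 and its adjusted p 0.0552 to 0.171.

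The first pattern weighed is the fall of ribosomal protein genes in both lines. Ribosomal protein transcripts are short (median 738 bases). Removal of the trend with length and GC of other protein-coding genes took their median from -1.30 to -1.15 in WiT49 and from -1.39 to -1.14 in HEK293. That trend is therefore not the whole cause. Reads did not move to pseudogenes, whose share of counts fell too (-0.0244 percentage points in the line with the smaller loss), and scaling by library size alone left a median of -1.05 or lower in each line and subunit. Some other short transcripts fell in the same libraries: 4 chosen short RNAs went from 11.7% to 7.59% of counts in WiT49 and from 13.9% to 6.68% in HEK293, and histone genes had medians of -1.22 and -1.01. In WiT49 the falls of the 4 short RNAs were uneven, from -0.36 for RMRP to -1.29 for RPPH1. A shared technical loss of short RNAs, a change in the amount of RNA per cell, for which no spike-in was named, and a biological loss of this class of mRNA may each contribute, and all stay open.

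The second pattern is the interferon-stimulated genes, lower under QC6352 in HEK293 (adjusted p = 0.00261, or 0.619 with an estimated correlation) and not called in WiT49; the difference between lines also lost its call there (0.356). The HEK293 controls were uneven, with IFIT1 counts of 2293, 1032 and 1732 against 252 to 336 under treatment, and IFI44L counts of 567, 128 and 370 against 3 to 16. Leaving out each HEK293 control in turn kept the median difference at 0.66 or higher, which argues against a single control library as the cause. It does not address unevenness across all 3 controls. The 4 abundant short RNAs ranked these controls the same way, with 16.7%, 11.1% and 13.8% of counts in replicates 1, 2 and 3. Over the 32 members at 1 CPM or more in both controls the median difference was 0.73 (22 higher and 3 lower), which argues against genes near the floor. A response of the line to the compound, or a control culture with interferon signalling of its own, may each account for it, and these were not tested.

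The third pattern is cholesterol synthesis, which fell more in HEK293. Its median difference was at least 0.448 without any 1 of the 12 libraries, which argues against a single library. Under 4 scalings it was at least 0.45 (0.453 with library size alone). A scaling shifts all genes nearly alike, and library size alone moved the median difference of all genes only from -0.01 to -0.07. The choice among these scalings thus does not account for the difference, and composition was not tested otherwise. Medium and serum differed with the line, and serum carries cholesterol, so line and medium cannot be told apart here. A difference between the lines themselves stays open and untested.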

How the results depend on the processing

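The restriction to protein-coding genes and the upper quartile and library-size scalings of list tests were chosen only after the results were seen. The counts of genes past the threshold stayed within 1.5 times of the main ones under all alternatives run; without 1 library in turn they ran from 14180 to 15034 in WiT49, 12534 to 14187 in HEK293 and 8771 to 10387 for the difference. Counts at 2-fold moved with a stricter filter, to 2365 from 4405 in WiT49 and 2425 from 4388 in HEK293, and with protein-coding genes alone, to 2353, 2351 and, for the difference, 2003 from 3028, since fewer genes were tested. Library size alone reversed KDM4B (0.22) and DDX21 (0.065) in WiT49 and WDR36 (0.26) and LEF1 (0.32) in HEK293, all shifted by the move of all genes. KDM4C in HEK293 passed with upper quartile factors (0.22), library size alone (0.46), a stricter filter (0.17) and all 12 libraries in 1 fit (0.16). The KDM4A difference passed with a stricter filter (0.20), with protein-coding genes (0.23) and without HEK293 DMSO replicate 1 (0.21; 0.13 to 0.21 over all left-out libraries). KDM4D in WiT49 did not pass without DMSO replicate 3 (0.20; 0.20 to 0.27 over all). For the KDM4 genes the cause was not tested. With an estimated correlation camera called 0, 0 and 1 lists in place of 14, 19 and 13. A call lost at that setting does not by itself show correlation above the preset 0.01. The estimate was -0.016 for translation factors in HEK293 and -0.013 for other JmjC demethylases in WiT49, which lost their calls too. For other lists it was higher, such as 0.66 for large subunit ribosomal proteins in WiT49. The fry test, which does not compare a list with other genes, called 31, 31 and 22. Of the other values of named genes, 5597 kept their side of the threshold, 53 gained a call, 25 lost it and 3 reversed. Directions were compared only where a gene passed in the main or the alternative fit, so genes without a call may have changed sign.
The labels number the libraries of each group 1 to 3, but these numbers do not pair them: same-numbered DMSO and QC6352 libraries correlated at -0.06 to 0.04 after removal of group means. With the replicate number as a block, 15158, 13395 and 9214 genes passed, 7802 alike in both lines, and of the list calls only translation factors and WNT targets in the difference were lost (both adjusted p = 0.0728), and immune cell markers in HEK293 were gained (0.0370). Genes with very few counts, such as KDM4E, did not pass the filter and were not tested with the main settings.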

Other observations

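The tests of the lists and the genes named in this part were chosen after the results were seen. The fall of ribosomal protein and elongation factor genes raised the hypothesis that mRNAs with a terminal oligopyrimidine start, which are translated together with them, share it. Of 13 tested genes of this kind outside the ribosome, 12 were lower and 1 higher in WiT49 (median -1.03) and 10 lower and 1 higher in HEK293 (median -1.02). HNRNPA1, a splicing regulator, fell by 1.44 ± 0.04 in WiT49 and 1.33 ± 0.06 in HEK293 (SE, n = 3 per group), and NAP1L1, a histone chaperone, by 1.17 ± 0.04 and 1.29 ± 0.06. TPT1 fell by 1.07 ± 0.05 and 1.28 ± 0.10 and EEF1D, a subunit of the exchange factor of EEF1A1, by 1.40 ± 0.05 and 1.08 ± 0.06. The elongation factor EEF2 fell by 1.03 ± 0.04 in WiT49 but did not pass in HEK293 (-0.14 ± 0.09, adjusted p = 0.210 in edgeR's quasi-likelihood test). The members that rose were TMEM59 in WiT49 (0.55 ± 0.04) and IPO7 in HEK293 (0.16 ± 0.06). Camera's adjusted p was 3.64e-05 in WiT49 and 2.45e-04 in HEK293 (1.21e-05 and 8.15e-05 before adjustment), or 0.276 and 0.148 with an estimated correlation. This list shares members with the translation factors, already seen to fall, and so decides nothing. Of the 8 genes that are not translation factors, VIM is also in the extracellular matrix and EMT list, whose results had been seen. Over these 8 genes, 7 were lower and 1 higher in WiT49 (median -0.64) and 6 lower and 1 higher in HEK293 (median -0.98). For these camera's adjusted p over 3 lists was 0.00517 and 0.00821 (0.00345 and 0.00547 before adjustment), and adjusted p = 0.276 and 0.298 with an estimated correlation. A fall shared by this class of mRNA may extend past ribosome and translation factors at the preset correlation, and the estimated correlation does not bear it out.

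CTGF, CYR61 and ANKRD1 are known targets of YAP and TEAD, and all rose in both lines. This raised the hypothesis that targets of these factors rise as a group. Over 18 other listed targets, 11 were higher and 4 lower in WiT49 (median 0.49) and 10 higher and 4 lower in HEK293 (median 0.41). Of these targets TGFB2, like CTGF and CYR61, is also in the extracellular matrix and EMT list, whose results had been seen. IGFBP3 rose by 1.25 ± 0.04 and 2.65 ± 0.10, AMOTL2 by 1.05 ± 0.05 and 1.71 ± 0.08 and TGFB2 by 1.38 ± 0.06 and 0.76 ± 0.11, whereas NT5E fell by 1.38 ± 0.10 and 1.03 ± 0.15. Camera gave p = 0.0287 in WiT49 and 0.0847 in HEK293, with adjusted p = 0.276 and 0.503 with an estimated correlation, so a shared rise of this group may hold in WiT49 and could not be shown in HEK293.

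Short structural RNAs were lower under QC6352 in both lines. RN7SL1, the RNA of the signal recognition particle, was at -1.06 ± 0.06 in WiT49 and -1.80 ± 0.17 in HEK293, and RPPH1, the RNA of ribonuclease P, at -1.29 ± 0.05 and -1.57 ± 0.14. RN7SK was at -0.70 ± 0.05 and -1.04 ± 0.12, and RMRP at -0.36 ± 0.05 and -1.44 ± 0.12, so the falls were uneven in WiT49. Long noncoding genes by GENCODE 29 were higher in 485 and lower in 289 of 1275 in WiT49 and higher in 491 and lower in 251 of 1298 in HEK293. Pseudogenes were higher in 358 and lower in 420 of 1454 and higher in 265 and lower in 479 of 1460. The few matched genes of other types did not fall as a class. They were higher in 14 and lower in 15 of 47 in WiT49 and higher in 22 and lower in 14 of 55 in HEK293. Among protein-coding genes changed at least 2-fold, 1115 were higher and 1250 lower in WiT49, and 1572 higher and 775 lower in HEK293.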
